A study of Mus musculus with 16 samples.

How the data were processed

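Bulk RNA sequencing was done on hearts of male C57BL/6 mice that had eaten 1 of 4 diets for 6 months, starting at 6 weeks of age. The 16 libraries were poly-A selected and stranded, came from RNA with an integrity number above 7.0, and were read on a NextSeq as 75-base single reads. RNA came from the lower part of the ventricles, and each library is a single animal. Per the labels, the animals were assigned to the diets at random.

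The deposited file holds expected counts per gene, which the authors' notes tie to BWA, DESeq2 and the mouse genome build mm10 without giving versions, the counting tool or the gene models. The values were not scaled: the library sums differ, and between 13% and 52.4% of the values of a library are not whole numbers. The file lists 17737 genes by symbol, with no gene of the mitochondrial genome and no gene whose values sum to fewer than 10 over the 16 libraries. Values were rounded to whole counts. Positions are those of the file on mm10, counted from 1, and transcript lengths and sequences came from GENCODE vM21 on the same build.

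Groups follow the diet named in the sample titles, which matches the diet label of each sample. The library codes do not spell those diets: chow libraries carry the code CC, NIA libraries MNC, UW libraries NC and mNIA libraries UC. Which of the 3 primate-formula groups is which was therefore left open, and the mean of the 3 was compared with chow as a contrast that does not depend on it. Each comparison of a single primate-formula group rests on the titles, and would belong to other diets if the groups were exchanged. By their letters alone, NC could be read as NIA, MNC as mNIA and UC as UW, which was not settled. Under that reading the groups titled mNIA and UW would be the unmodified formulas. Those titled mNIA and NIA would be the pair sharing sucrose and fat.

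Differential expression was tested with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the diet as group, which left 13381 genes, 75.4% of the file. Libraries were scaled by TMM, and a quasi-likelihood negative binomial model with robust dispersion shrinkage was fitted with 1 mean per diet and no covariate, since no batch is labelled. Tests were 2-sided, p-values were adjusted over all tested genes of a contrast by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. The contrasts were the 6 pairs of diets, the mean of the 3 primate-formula diets minus chow, and a joint test for any diet difference. The square root of the common dispersion was 0.28. Log2 fold changes are given with the standard error (SE) of the model and, where stated, a 95% confidence interval. Expression is given as TMM-scaled CPM, as mean ± SD over 4 animals.

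Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. There were 58 lists, written before the data were examined, as were the contrasts, the test, the named-gene rule and most of the other settings. The 54 lists with at least 5 tested members were used, and p-values were adjusted over the 54 lists of a contrast. Each list was also tested by camera with an estimated correlation and by fry, which asks whether the genes of a list move 1 way on balance. Each list that passed was also refitted without each library of its comparison in turn, and the libraries named beside a list were picked after their values were seen. A fit without 1 library cannot test a call that rests on several libraries together. Members are also counted with p-values adjusted over the list alone. These p-values are not corrected over the 54 lists or the 7 contrasts, so some members pass by chance. A gene in several lists is counted in each. The 4 lists left out held 4 tested granulocyte and mast cell markers, 1 lung and airway marker, 4 skeletal muscle markers and 0 oxidative phosphorylation genes of the mitochondrial genome.

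Genes were named by a fixed rule. It took, per contrast, up to 12 higher and 12 lower genes past the threshold with the smallest p, given a symbol other than a clone name and a mean of at least 1 CPM in a compared group. It added the 4 members with the smallest p of each list that passed camera, and 20 fixed genes whether they passed or not. Adipoq, 1 of those 20, was filtered out. Genes outside the rule are described as chosen after their values were seen. Values of 2 genes are not reported here, and these were left out of the comparison of single libraries with their group.

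The other settings chosen in advance were RLE size factors, upper-quartile scaling, the tests of DESeq2 1.42.0 and of limma-voom with sample quality weights, no filter, a filter of over 1 CPM in at least 4 libraries, the replicate number as a block, removal of the 10 genes with most counts, fits of 2 groups alone, and removal of each library in turn. Chosen after seeing the data were removal of 4 libraries with a quality weight under 0.5 (leaving 3 chow, 2 NIA, 4 UW and 3 mNIA), 3 surrogate variables from sva 3.50.0, the code number as a block, binomial thinning of NIA replicate 2 to a total of 5 M (mega) counts, and removal of 409 tested genes whose transcripts hold an A or T run of at least 25 bases.

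The pipeline was tested on simulated data with the dispersions and library sizes of these libraries. Among 13381 simulated genes, between 27% and 45% of 2-fold changes and between 84% and 94% of 4-fold changes were recovered over the 6 pairs of diets. A simulated 1.5-fold rise of 1 list of ribosomal protein genes passed camera in all 6 pairs, with a largest adjusted p of 0.000244 with an estimated correlation. Genes were drawn independently, without the correlation between genes or the library structure of the real data. The simulation therefore does not show how either form of camera behaves on the real lists, and recovery of real changes may differ. Total counts per library ranged from 2278250 to 63005490, with a median of 5.22 M. Intervals on counts cover counting error alone.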

Results

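Gene expression was measured in the ventricles of 16 mice, 4 on each of 4 diets, to ask how diet bears on cardiac ageing and fibrosis. The diets were a laboratory chow and 2 formulas made for primates, NIA and UW in the labels. The last was mNIA, an NIA formula altered to carry the sucrose and fat of UW. These names follow the sample titles, and the library codes leave open which primate-formula group is which. Total counts per library ran from 4263827 to 5953964 in chow, from 4880235 to 6583532 in UW and from 3870480 to 6544172 in mNIA. In NIA, replicate 2 held 63005490 counts, 27.7 times the 2278250 of replicate 4. The first 3 principal components held 42.3%, 23.8% and 9.3% of the variance of log2 CPM.

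Some libraries stood apart on measures other than diet. Genes whose transcripts hold an A or T run of at least 25 bases took 24.2% of the counts of NIA replicate 1 and 26.6% of those of NIA replicate 4. In the other libraries they took 6.09% to 14.2%. Across genes, the level of NIA replicate 4 relative to each gene's median over the 16 libraries fell with transcript length (Spearman rho -0.47). That of UW replicate 4 rose with it (rho 0.45). Genes are not independent replicates, so no p-value is given. The limma quality weight was under 0.5 in 4 libraries: chow replicate 3 (0.23), NIA replicate 1 (0.3), NIA replicate 4 (0.16) and mNIA replicate 2 (0.36). This weight is estimated from the same counts and is low where a library lies far from the mean of its diet. Removing such libraries narrows the spread within diets by construction, so more calls without them are no independent support. Endothelial markers and citric acid cycle genes also parted libraries within every diet, with values given under the flagged results. How far list differences between diets follow this structure was not tested.

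**Figure D1:**
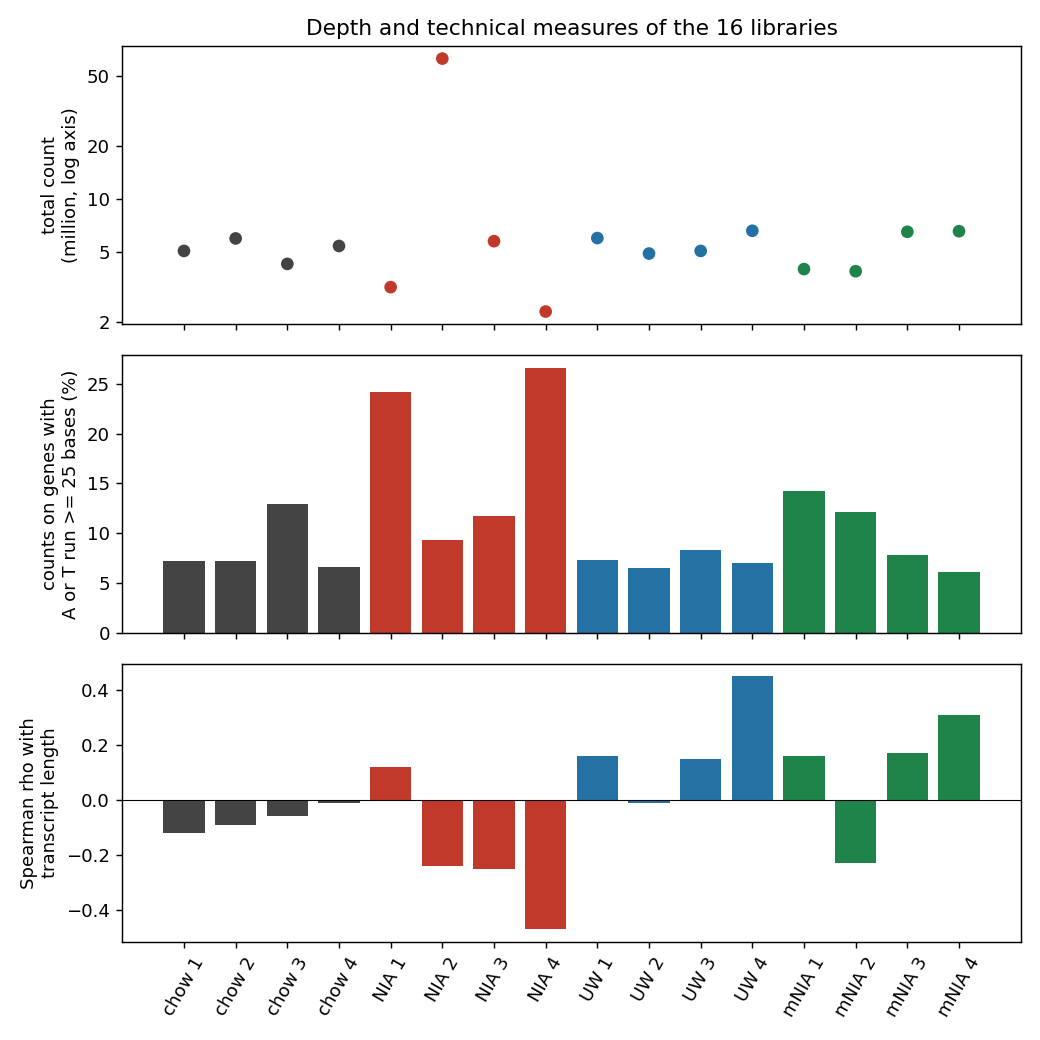
Depth and technical measures of each of the 16 libraries, coloured by diet: total count on a log axis, percent of counts on genes with an A or T run of at least 25 bases, and Spearman rho across genes between the library's relative level and transcript length. NIA replicate 2 has 63005490 counts, and NIA replicates 1 and 4 have 24.2% and 26.6% of counts on long-run genes.

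None of the 19 tested fixed genes, most of them markers of cardiac stress, fibrosis and lipid use, passed in any comparison of diets. Col1a1, which encodes a chain of type I collagen (chromosome 11, 94936224 to 94953042), was at 137 ± 21.4 CPM in chow (SD, n = 4), 110 ± 48 in NIA, 132 ± 45.1 in UW and 107 ± 15.2 in mNIA. Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000722 to 148002074), was at 138 ± 59.8 CPM in chow, 93.5 ± 33.1 in NIA, 111 ± 34.4 in UW and 138 ± 46.2 in mNIA. For the mean of the 3 primate-formula diets minus chow, the log2 fold change of Col1a1 was -0.24 (95% confidence interval -0.76 to 0.28). For Col3a1 it was -0.06 (interval -0.51 to 0.39) and for the matrix protein gene Postn -0.09 (interval -0.45 to 0.27). For Nppa it was -0.30 (interval -0.84 to 0.25), and for Myh7, the slow myosin heavy chain, -0.06 (interval -0.75 to 0.64).

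**Figure D2:**
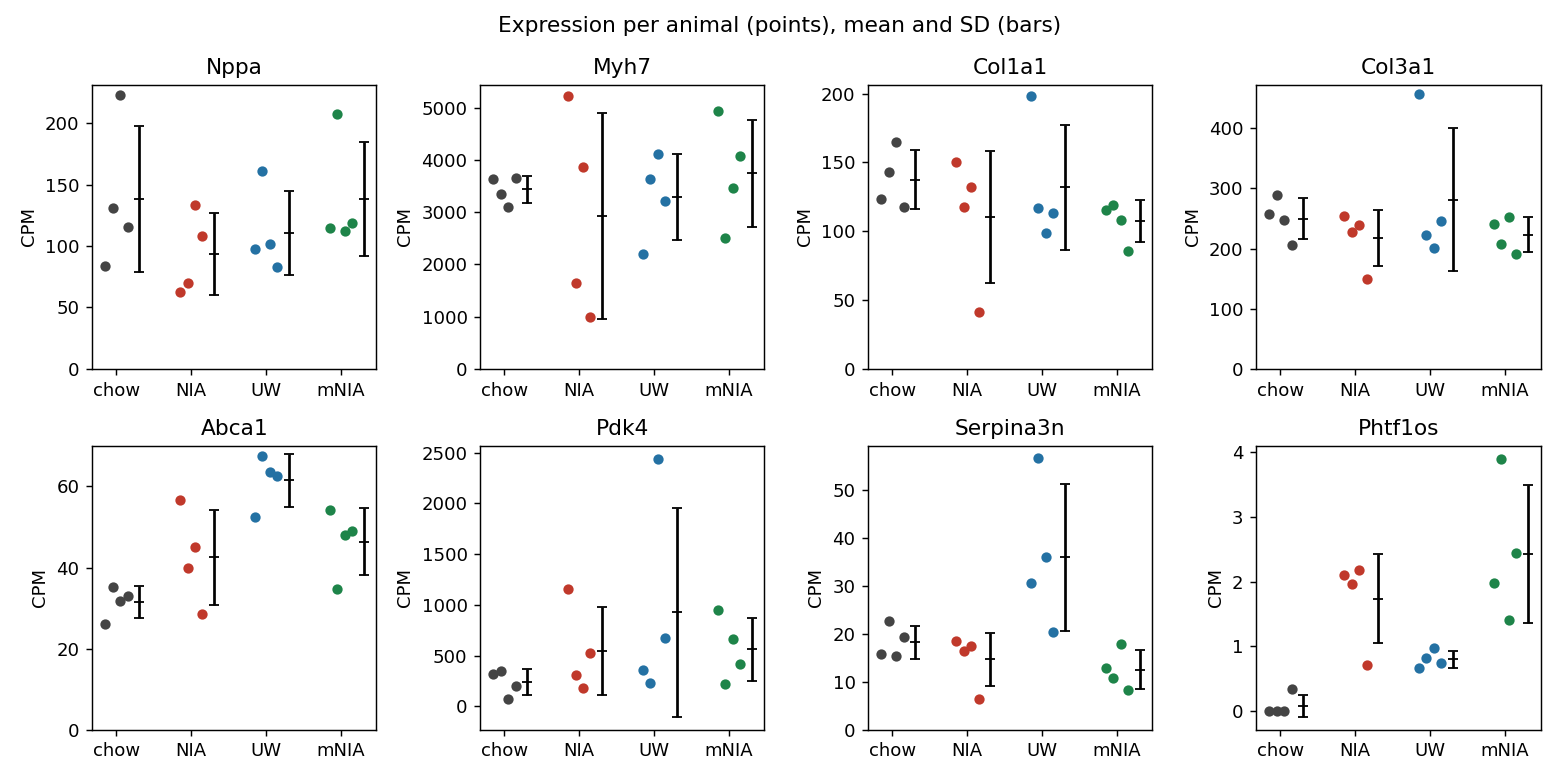
Expression of 8 genes in CPM, 1 point per animal, with the mean and SD of the 4 animals of each diet as bars. Abca1, Serpina3n and Phtf1os were chosen after their values were seen; all 4 UW animals lie above all 4 chow animals for Abca1 and Phtf1os.

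In the comparison of all 3 primate-formula diets with chow, gene groups of antigen presentation were lower and those of fat use were higher on the primate formulas. All 18 antigen presentation genes had a lower mean on the primate formulas (median log2 fold change -0.42, camera adjusted p = 5.5e-05), among them Tap1, a peptide transporter (-0.69 ± 0.35, SE), and Tap2 (-0.51 ± 0.24). Of the 9 lists that passed in this comparison 0 did so when the correlation was estimated (smallest adjusted p = 0.851 with an estimated correlation). Of 34 genes of fatty acid oxidation and PPAR targets, 30 were higher (median 0.23, adjusted p = 0.000104), with Pdk4, a brake on glucose oxidation, at 1.48 ± 0.62 and Acot2, a mitochondrial thioesterase, at 0.65 ± 0.31. All 18 chaperone and heat shock genes were higher (median 0.24, adjusted p = 0.000713), and 29 of 32 interferon response genes were lower (median -0.28, adjusted p = 0.000182). Markers of other cell types were lower in the same comparison: 14 of 15 for erythrocytes and platelets (median -0.46, adjusted p = 0.00194), 12 of 15 for pericytes and smooth muscle (median -0.35, adjusted p = 0.00989) and 15 of 18 for endothelium (median -0.27, adjusted p = 0.0302). Of 17 basement membrane genes 15 were lower (median -0.19, adjusted p = 0.00734), and 18 of 19 glucocorticoid response genes were higher (median 0.35, adjusted p = 0.00764).

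Much of this rested on chow replicate 3, a library of low quality weight, and 6 of the 9 lists no longer passed without it. The list level, which is the median over members of log2 CPM minus the mean of each gene, was 0.99 in chow replicate 3 for interferon response (other chow animals -0.04 to 0.09) and -0.91 for fatty acid oxidation (others -0.01 to 0.12). Without that library the median log2 fold change was 0.01 for interferon response (adjusted p = 0.73) and 0.05 for fatty acid oxidation (adjusted p = 0.788). The median of chaperone genes was then 0.16 (adjusted p = 0.0754), and the lists of endothelium, pericytes and smooth muscle, and erythrocytes and platelets were lost too. Antigen presentation (median -0.13, adjusted p = 0.0317), basement membrane (median -0.11, adjusted p = 0.0416) and glucocorticoid response genes (median 0.41, adjusted p = 0.000264) still passed. The first 2 passed without any 1 of the 16 libraries, while glucocorticoid response was lost without chow replicate 4 or UW replicate 3 and endothelial markers in 7 of the 16 fits.

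Of the 54 lists, 9 passed camera in that comparison. Without the count filter 14 passed, and without chow replicate 1 there were 16. In edgeR 0 of 13381 genes passed (293 had an unadjusted p under 0.05, against 669 by chance). DESeq2 called 0 and limma-voom 4 (Abca1, Gdf10, Nedd9 and Phtf1os, chosen after their values were seen). Adjusted over the list alone, 2 members passed: Abca1 in the LXR and cholesterol efflux list and Cyp26b1, which breaks down retinoic acid, in the list of vitamin A, thyroid and nuclear hormone targets. The lists of fibrillar collagen and matrix (adjusted p = 0.232), profibrotic signalling (0.185) and cardiac stress genes (0.369) did not pass. In the joint test for any diet difference edgeR called 0 genes (920 with an unadjusted p under 0.05, against 669 by chance), DESeq2 174 and limma-voom 1980. Without NIA replicate 2 edgeR called 110, without UW replicate 3 it called 1 (Cyp1a1, chosen after its values were seen), and without the 4 libraries of low quality weight 1374.

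Hearts on NIA were compared with hearts on chow. Genes of the protein synthesis machinery and of mitochondrial respiration had higher means on NIA: 36 of 37 cytosolic ribosomal protein genes (median log2 fold change 0.67, camera adjusted p = 9.61e-10) and 38 of 44 nuclear genes of oxidative phosphorylation (median 0.62, adjusted p = 2.98e-08). Estimating the correlation left 0 of the 9 lists of NIA against chow (smallest adjusted p = 0.984 with an estimated correlation). Rpl35 was at 221 ± 49.4 CPM in chow and 603 ± 585 in NIA, and Cox7a1, a subunit of cytochrome c oxidase, at 538 ± 73.1 and 1441 ± 1452. NIA replicate 4, with the fewest counts, was at 1480 CPM for Rpl35 against 255 to 351 in the other NIA animals, and at 3610 for Cox7a1 against 579 to 809. Without that library the median was 0.17 for ribosomal protein genes (adjusted p = 0.00518) and 0.10 for oxidative phosphorylation (adjusted p = 0.0198). The level of ribosomal protein genes in NIA replicate 1 was -0.436, below all chow animals (-0.259 to 0.145). Of 17 basement membrane genes, 16 were lower on NIA (median -0.45, adjusted p = 0.000116). Their list level was -1.51 in NIA replicate 4 against -0.18 to 0.17 in the other NIA animals, and without it the median was -0.24 (adjusted p = 0.00518). Lamb2, a laminin chain, was at 356 ± 18.9 CPM in chow and 240 ± 66.7 in NIA, lower in 4 of 4 NIA animals than in any chow animal. Hspg2, or perlecan, had a log2 fold change of -0.89 ± 0.41.

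Smaller shifts on NIA took in immune and lipid genes. Interferon response genes were lower in 28 of 32 cases (median -0.31, camera adjusted p = 0.00933) and antigen presentation genes in 16 of 18 (median -0.25, adjusted p = 0.0263). The NIA animals went both ways. The interferon level was -0.735 and -0.374 in NIA replicates 1 and 4 but 0.257 and 0.37 in replicates 2 and 3. For antigen presentation it was -1.026 and -0.522 against 0.322 and 0.729. Pericyte and smooth muscle markers were lower in 11 of 15 cases (median -0.27, adjusted p = 0.0397). Fatty acid synthesis genes were lower in 16 of 21 (median -0.26, adjusted p = 0.0445), with Acaca, which makes malonyl-CoA, at -0.90 ± 0.32. NRF2 and antioxidant genes were higher in 24 of 29 cases (median 0.24, adjusted p = 0.0132) and fatty acid oxidation genes in 26 of 34 (median 0.24, adjusted p = 0.0161), with the fatty acid carrier Fabp3 at 0.74 ± 0.34. Nppb, which encodes brain natriuretic peptide, was at 132 ± 28 CPM in chow and 290 ± 232 in NIA, and did not pass (adjusted p = 0.475). Without chow replicate 3 the 6 lists of this paragraph no longer passed, each was also lost without at least 1 other library, and with an estimated correlation 0 did (smallest adjusted p = 0.984 with an estimated correlation). With p-values adjusted over the list alone 4 genes passed, each with a higher mean on NIA and chosen after its values were seen: Bhlhe41 in the clock list, Hspe1 among chaperones, Cox7a1 among brown adipocyte markers and Plau in matrix turnover. Bhlhe41 was at 3640 and 4481 CPM in NIA replicates 1 and 4, which hold the largest shares of counts on long-run genes. It was at 483 and 768 in replicates 2 and 3, against 373 to 707 in chow. Hspe1 and Cox7a1 were highest in NIA replicate 4 (661 and 3610 CPM), against 106 to 187 and 579 to 809 in the other NIA animals. Plau lay above all chow animals in 2 NIA animals.

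In edgeR 0 of 13381 genes passed between NIA and chow (1164 with an unadjusted p under 0.05, 872 higher and 292 lower, against 669 by chance), DESeq2 called 127 and limma-voom 28. Without NIA replicate 2 edgeR called 116, and without the 4 libraries of low quality weight 224. Without NIA replicate 1 there were 5 lists, and without the 4 libraries 19. None of the 19 tested fixed genes passed (adjusted p from 0.475 to 0.989).

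Hearts on UW were compared with hearts on chow. Abca1, the transporter that exports cholesterol from cells (chromosome 4, 53030789 to 53159895, minus strand), was at 31.5 ± 3.98 CPM in chow and 61.5 ± 6.47 in UW, a log2 fold change of 0.96 ± 0.20 with all 4 UW animals above all chow animals. Mylip, which marks the LDL receptor for breakdown, was at 22.4 ± 1.56 and 36.5 ± 7.76 CPM, again with 4 of 4 UW animals above chow. Both belong to the LXR and cholesterol efflux list, of which 5 of 10 members were higher (median 0.09, camera adjusted p = 0.0441), a call lost without any 1 of 5 of the 8 libraries and with an estimated correlation (smallest adjusted p of any list = 0.537 with an estimated correlation). Neither passed over all genes (adjusted p = 0.977), whereas adjusted over the list alone the p-values were 0.00159 and 0.00509, with no correction over the 54 lists or the 7 contrasts. Abca1 was the 1 gene that DESeq2 called and the 1 gene that limma-voom called.

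Stress hormone, acute phase and fat-use genes were also higher on UW. Of 19 glucocorticoid response genes 17 were higher (median 0.50, camera adjusted p = 3.1e-05), among them Mt2, a metallothionein (6.75 ± 3.71 CPM in chow, 23.7 ± 17.2 in UW), and Cdkn1a, a cell cycle inhibitor (1.06 ± 0.42). With an estimated correlation 0 of the 19 lists of UW against chow passed (smallest adjusted p = 0.537 with an estimated correlation). The glucocorticoid list level was 0.66 and 0.93 in UW replicates 2 and 3 and -0.29 and -0.03 in replicates 1 and 4. In chow it was -0.27 to 0.00. The list passed without any 1 of the 8 libraries, at the weakest without UW replicate 3 (median 0.28, adjusted p = 0.0461). Such fits keep UW replicate 2 or 3, so they cannot test a call that rests on both. All 13 acute phase and complement genes were higher (median 0.37, adjusted p = 0.003), with C4b at 16.7 ± 4.75 and 38.5 ± 24.1 CPM and C3 at 0.87 ± 0.35. That level was 0.83 and 0.84 in UW replicates 1 and 2 and -0.06 and -0.19 in replicates 3 and 4, against -0.19 to 0.15 in chow, and the call was lost without UW replicate 1 (median 0.22, adjusted p = 0.156). Fatty acid oxidation genes were higher in 29 of 34 cases (median 0.23, adjusted p = 0.00149), with Pdk4 at 236 ± 128 CPM in chow and 926 ± 1027 in UW, a call lost without chow replicate 3 (median 0.03, adjusted p = 0.978) or UW replicate 3 (median 0.08, adjusted p = 0.534). Chaperone genes were higher in 16 of 18 cases (median 0.27, adjusted p = 0.00149). Their level was -0.58 in chow replicate 3 (other chow animals -0.14 to 0.01), and without it the median was 0.16 (adjusted p = 0.044). Lists of insulin signalling, the unfolded protein response, immediate early genes, metal handling, vitamin A and thyroid targets, mitochondrial biogenesis and epicardial markers were higher too, with medians of 0.14 to 0.49 and adjusted p of 0.00735 to 0.0493. Of these, only metal handling passed without any 1 of the 8 libraries.

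Blood cell markers were lower on UW: 13 of 15 erythrocyte and platelet genes (median -0.81, camera adjusted p = 7.8e-07), with the beta globin gene Hbb-bs at 644 ± 269 CPM in chow and 321 ± 165 in UW. No list of UW against chow passed when the correlation was estimated (smallest adjusted p = 0.537 with an estimated correlation). Globin genes are near copies of one another, so their reads are hard to assign to 1 gene. Antigen presentation genes were lower in 15 of 18 cases (median -0.29, adjusted p = 0.00735) and oxidative phosphorylation genes in 36 of 44 (median -0.20, adjusted p = 0.00144), the first lost without chow replicate 3 (median -0.02, adjusted p = 0.309) or UW replicate 3 or 4 and the second without UW replicate 1 (median -0.12, adjusted p = 0.123). Interferon response genes, ribosomal protein genes, lymphocyte markers and pericyte and smooth muscle markers were lower too, with medians of -0.40 to -0.14 and adjusted p of 0.0117 to 0.0369, and all 4 were lost without chow replicate 3. In edgeR 0 genes passed between UW and chow (315 with an unadjusted p under 0.05, against 669 by chance). Without UW replicate 2, 11 lists passed. Only 4 of the 19 lists passed without any 1 of the 8 libraries (glucocorticoid response, chaperones, metal handling, and erythrocyte and platelet markers), and the other 15 were each lost in 1 to 5 of these fits. With p-values adjusted over the list alone, 12 memberships passed in 10 lists, among them Ctgf, a matrix and growth factor binding protein, at 1.01 ± 0.28 in the profibrotic and cardiac stress lists. Ctgf was chosen after its values were seen, and neither of these lists passed camera between UW and chow.

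Hearts on mNIA were compared with hearts on chow. Immune genes had lower means on mNIA, among them all 18 antigen presentation genes (median log2 fold change -0.61, camera adjusted p = 2.09e-07). With an estimated correlation 0 of the 18 lists of mNIA against chow passed (smallest adjusted p = 0.718 with an estimated correlation). Without chow replicate 3, whose antigen presentation level was 0.87 (other chow animals 0.06 to 0.22), the median of that list was -0.28 (adjusted p = 0.000663). Also lower were 21 of 23 macrophage and monocyte markers (median -0.45, adjusted p = 3.46e-05) and 15 of 16 tested cytokines and chemokines (median -0.29, adjusted p = 0.000196). H2-Ab1, a class II antigen-presenting molecule, was at 39.5 ± 6.85 CPM in chow and 26 ± 3.13 in mNIA, lower in 4 of 4 mNIA animals than in any chow animal. Lists tied to fibrosis were lower as well, with 17 of 21 profibrotic signalling genes (median -0.25, adjusted p = 0.000515) and 25 of 29 fibrillar collagen and matrix genes (median -0.16, adjusted p = 0.00536). Profibrotic signalling was at 0.55 in chow replicate 3 (other chow animals -0.10 to 0.01), and without it the medians were -0.08 for this list and -0.08 for fibrillar collagen (adjusted p = 0.0207 for each). The call of fibrillar collagen was lost without mNIA replicate 4 (median -0.12, adjusted p = 0.0958), and so was that of cytokines and chemokines (median -0.21, adjusted p = 0.0665). Matrix turnover genes were lower in 14 of 21 cases (median -0.16, adjusted p = 0.0333), and fibroblast markers in 15 of 18 (median -0.18, adjusted p = 0.0297), calls lost without any 1 of 5 and of 4 libraries. Tnc, which encodes tenascin C, was at -1.37 ± 0.50 and Timp1, a protease inhibitor, at -1.45 ± 0.54.

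Muscle and fuel genes had higher means on mNIA, for most of these lists through chow replicate 3. Of 34 fatty acid oxidation genes 31 were higher (median 0.26, camera adjusted p = 0.000196), and of 18 chaperone genes 16 (median 0.33, adjusted p = 0.000487). Contractile genes were higher in 19 of 21 cases (median 0.19, adjusted p = 0.0176), citric acid cycle genes in 17 of 19 (median 0.25, adjusted p = 0.00628) and insulin signalling genes in 18 of 24 (median 0.13, adjusted p = 0.0333). The level of the citric acid cycle was -1.21 in chow replicate 3 against 0.11 to 0.26 in the other chow animals. Without that library the median was -0.02 for the citric acid cycle (adjusted p = 0.289), 0.08 for fatty acid oxidation (adjusted p = 0.764), 0.07 for contractile genes (adjusted p = 0.771) and 0.12 for insulin signalling (adjusted p = 0.412), and the chaperones still passed (median 0.23, adjusted p = 0.0339). Without mNIA replicate 4 the chaperones were lost (median 0.20, adjusted p = 0.0963), as were the contractile, citric acid cycle and insulin signalling lists. Interferon response genes were lower in 28 of 32 cases (median -0.29, adjusted p = 0.000358) and erythrocyte and platelet markers in 14 of 15 (median -0.57, adjusted p = 0.000273), the first lost without chow replicate 3 (median 0.04, adjusted p = 0.716). Immediate early genes, amino acid stress genes, endothelial markers and thymus and lymph node markers were lower too, with medians of -0.33 to -0.12 and adjusted p of 0.00628 to 0.0196. Phgdh, an enzyme of serine synthesis, was at -1.26 ± 0.42 and Egr1 at -1.55 ± 0.58. Of the 18 lists 0 passed with an estimated correlation (smallest adjusted p = 0.718 with an estimated correlation). Only 5 passed without any 1 of the 8 libraries (antigen presentation, macrophage and monocyte markers, profibrotic signalling, amino acid stress, and erythrocyte and platelet markers), and the other 13 were each lost in 1 to 5 of these fits. At the weakest, the median was -0.28 for erythrocyte and platelet markers (without chow replicate 3, adjusted p = 0.0207), -0.29 for macrophage markers (without mNIA replicate 4, adjusted p = 0.00645) and -0.06 for amino acid stress (without chow replicate 2, adjusted p = 0.0454). Without chow replicate 3 there were 12 lists, without mNIA replicate 4 there were 7, and with 3 surrogate variables, added after seeing the data, 4.

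One gene passed the test of mNIA against chow. Phtf1os, an antisense transcript (chromosome 3, 103964536 to 103968316, minus strand), rose from 0.0845 ± 0.169 CPM in chow to 2.43 ± 1.07 in mNIA (adjusted p = 0.0451), higher in 4 of 4 mNIA animals than in any chow animal. It was at 1.74 ± 0.69 CPM in NIA and 0.8 ± 0.13 in UW, where it did not pass (adjusted p = 0.141 and 0.977). The 4 chow libraries held 2 counts of it together and the 4 mNIA libraries 48, a ratio of 26.1 after scaling (95% counting interval 6.83 to 221). This interval treats pooled, rounded counts as single reads. It leaves out the spread between animals and the sharing of reads between genes. The ends of Phtf1os overlap Rsbn1 (103914120 to 103966636) and Phtf1 (from 103968110), both on the plus strand. The counts of Phtf1os alone were whole numbers in 3 libraries, and those of the 3 genes together, within 0.01, in 15 of 16. Those of Phtf1 by itself were whole at 2 decimals in all but chow replicate 4 and UW replicate 4 (73.98 and 74.94). The fractions thus lay mostly between Phtf1os and Rsbn1. The call was lost (0 genes) in DESeq2, with upper-quartile scaling, in a fit of the 2 groups alone, with the replicate number as a block and without the 4 libraries of low quality weight. When 1 library at a time was left out, it was kept only without chow replicate 4 or mNIA replicate 3. In edgeR 185 genes had an unadjusted p under 0.05, against 669 by chance, and limma-voom called 1. The 1 member that passed when adjusted over the list alone was Cyp26b1 (3.69 ± 1.69 CPM in chow, 15.8 ± 8.64 in mNIA, chosen after its values were seen).

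By the titles, the unmodified primate formulas, NIA and UW, were compared with each other. Ribosomal protein genes were lower on UW than on NIA in 36 of 37 cases (median log2 fold change -0.85, camera adjusted p = 7.86e-14) and oxidative phosphorylation genes in 39 of 44 (median -0.90, adjusted p = 7.86e-14), with Rps24 at -1.52 ± 0.43 and Uqcrb at -1.44 ± 0.40. Estimating the correlation left 0 of the 7 lists of UW against NIA (smallest adjusted p = 0.905 with an estimated correlation). Without NIA replicate 4 the mean level of the 2 lists differed by -0.34 ± 0.17 (SE), against -0.71 ± 0.40 with it. Erythrocyte and platelet markers were lower in 12 of 15 cases (median -0.76, adjusted p = 0.00249), with Hbb-b1 at -1.46 ± 0.49. Higher on UW were 15 of 17 basement membrane genes (median 0.41, adjusted p = 0.00249) and 19 of 24 insulin signalling genes (median 0.35, adjusted p = 0.00249), the first lost without NIA replicate 4 (median 0.24, adjusted p = 0.0503) or UW replicate 1. Foxo3, a transcription factor held back by insulin, was at 1.94 ± 0.56. Fatty acid synthesis genes were higher in 15 of 21 cases (median 0.20, adjusted p = 0.0122), with Acaca at 1.16 ± 0.32 and the fatty acid synthase gene Fasn at 0.78 ± 0.25. Acute phase genes were higher in 12 of 13 (median 0.40, adjusted p = 0.0458), a call lost without NIA replicate 1 or UW replicate 1 or 2. Fatty acid synthesis was lost without NIA replicate 1, and erythrocyte and platelet markers without NIA replicate 2 or UW replicate 4. The ribosomal protein, oxidative phosphorylation and insulin signalling lists passed without any 1 of the 8 libraries, with medians of -0.32, -0.34 and 0.31 without NIA replicate 4. The Spearman rho of relative level with transcript length was -0.47 to 0.12 in NIA libraries and -0.01 to 0.45 in UW libraries. This trend was not weighed for insulin signalling, basement membrane or fatty acid synthesis genes, so it stays open for them.

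In edgeR 0 genes passed between UW and NIA (1858 with an unadjusted p under 0.05, against 669 by chance), DESeq2 called 375 and limma-voom 916. Without NIA replicate 2 edgeR called 217, without UW replicate 3 it called 1 (Cyp1a1), and without the 4 libraries of low quality weight 1627. Without the 4 libraries 18 lists passed. Counted with p adjusted over the list alone, 63 memberships passed, 27 of them in oxidative phosphorylation and 18 among ribosomal proteins.

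By the titles, the altered formula was compared with its parent, from which it differs in sucrose and fat by the labels. If the library codes were read by their letters, this pair would instead share sucrose and fat. Of 16 tested cytokines and chemokines, 14 had lower means on mNIA than on NIA (median log2 fold change -0.47, camera adjusted p = 1.19e-05). With an estimated correlation 0 of the 10 lists of mNIA against NIA passed (smallest adjusted p = 0.794 with an estimated correlation). Cxcl1, which draws neutrophils, was at 6.42 ± 3.68 CPM in NIA and 0.725 ± 0.228 in mNIA, and Ccl6 at 20.4 ± 9.19 and 8.38 ± 2.7 CPM. Macrophage and monocyte markers were lower in 21 of 23 cases (median -0.45, adjusted p = 0.00239), with the lysozyme gene Lyz2 at -0.87 ± 0.33. Ribosomal protein genes were lower in 36 of 37 cases (median -0.70, adjusted p = 3.88e-13) and oxidative phosphorylation genes in 37 of 44 (median -0.66, adjusted p = 1.6e-08). Their levels were 1.46 and 1.56 in NIA replicate 4, against -0.44 to 0.30 and -0.10 to 0.33 in the other NIA animals. Without it the medians were -0.19 (adjusted p = 0.000149) and -0.13 (adjusted p = 0.0406). NRF2 and antioxidant genes (25 of 29 lower, adjusted p = 0.000272), immediate early genes (19 of 24 lower, adjusted p = 0.00155) and erythrocyte and platelet markers (12 of 15 lower, adjusted p = 0.0157) had lower means too. All 20 ion channel genes were higher (median 0.39, adjusted p = 0.025), a call kept in 3 of 8 fits without 1 library, with the calcium channel gene Cacna1h at 0.64 ± 0.26. Insulin signalling genes were higher in 20 of 24 cases (median 0.33, adjusted p = 0.00155) and basement membrane genes in 14 of 17 (median 0.38, adjusted p = 0.00181), the latter lost without NIA replicate 4 (median 0.12, adjusted p = 0.136).

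In edgeR 0 genes passed between mNIA and NIA (1192 with an unadjusted p under 0.05, against 669 by chance), DESeq2 called 3 and limma-voom 1979. The 3 were Cmtr1, Cxcl1 and D830031N03Rik, chosen after their values were seen. Cmtr1, a cap methyltransferase gene, was at 22.7 ± 5.23 CPM in NIA and 47 ± 7.86 in mNIA, with 4 of 4 mNIA animals above all NIA animals. Of the lists 6 passed without NIA replicate 2. Cytokines and chemokines, ribosomal proteins, oxidative phosphorylation, NRF2 and insulin signalling passed without any 1 of the 8 libraries, NRF2 with a median of -0.14 without NIA replicate 4 (adjusted p = 0.0103). The trend on transcript length was not weighed for any of these lists between mNIA and NIA. Macrophage markers were lost without NIA replicate 2 or 3, and immediate early genes and erythrocyte and platelet markers each in 3 of the 8 fits. Without the 4 libraries of low quality weight 28 lists and 3184 genes passed, a removal that narrows the spread within diets by construction. When adjusted over the list alone, 9 memberships passed, 4 of them chemokines (Cxcl1, Ccl6, Ccl7 and Ccl9).

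The last pair, mNIA and UW by the titles, shared sucrose and fat content by the labels. If the library codes were read by their letters, it would instead be the unmodified formulas. All 23 macrophage and monocyte markers had lower means on mNIA than on UW (median log2 fold change -0.54, camera adjusted p = 1.4e-13). With an estimated correlation 0 of the 26 lists of mNIA against UW passed (smallest adjusted p = 0.0953 with an estimated correlation). Also lower were all 13 acute phase and complement genes (median -0.45, adjusted p = 4.71e-10) and 24 of 29 fibrillar collagen and matrix genes (median -0.29, adjusted p = 1.91e-06). The macrophage level was 0.74 and 0.52 in UW replicates 1 and 2 and -0.32 and -0.20 in replicates 3 and 4, and acute phase genes parted the same way. UW replicates 3 and 4 lay within the mNIA range for macrophage markers (-0.65 to 0.08) and acute phase genes (-0.32 to 0.06). Both lists passed without any 1 of the 8 libraries. Such fits keep UW replicate 1 or 2, so they cannot test a call that rests on both. Without UW replicate 1 their medians were -0.32 (adjusted p = 9.57e-05) and -0.30 (adjusted p = 0.000171). The level of fibrillar collagen was 0.65 in UW replicate 1 against -0.15 to 0.07 in the other UW animals, and the call was lost without it (median -0.01, adjusted p = 0.342). C1qb, a complement gene of macrophages, was at 49 ± 22 CPM in UW and 28.6 ± 5.36 in mNIA, and Lox, which links collagen fibres, at -0.81 ± 0.32. Serpina3n, an acute phase protease inhibitor, was at 36 ± 15.3 CPM in UW and 12.5 ± 4.08 in mNIA, and Ptx3, a pattern recognition protein, at 1.84 ± 0.803 and 0.1 ± 0.121. Both were lower in 4 of 4 mNIA animals than in any UW animal, and both were chosen after their values were seen. All 44 oxidative phosphorylation genes were higher on mNIA (median 0.23, adjusted p = 1.62e-07, and 0.14 without mNIA replicate 2), as were 19 of 21 contractile genes (median 0.17, adjusted p = 0.00796). Ribosomal protein genes were higher in 35 of 37 cases (median 0.16, adjusted p = 0.0282) and erythrocyte and platelet markers in 12 of 15 (median 0.28, adjusted p = 0.0355). These 2 lists were lost without UW replicate 3 or 4 or mNIA replicate 2, and contractile genes without UW replicate 1 or mNIA replicate 1 or 4.

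Immediate early genes were lower on mNIA than on UW in 20 of 24 cases (median -0.31, camera adjusted p = 2.01e-12), with Fos at -1.73 ± 0.63. Glucocorticoid response genes were lower in 18 of 19 (median -0.34, adjusted p = 6.29e-07) and cytokines and chemokines in 14 of 16 (median -0.37, adjusted p = 5.55e-08). None of these lists passed when the correlation was estimated (smallest adjusted p = 0.0953 with an estimated correlation). Among fibrosis lists, matrix turnover (18 of 21 lower, adjusted p = 7.95e-05), profibrotic signalling (15 of 21 lower, adjusted p = 0.000119) and fibroblast markers (15 of 18 lower, adjusted p = 0.000617) had lower means. Without UW replicate 1 matrix turnover (adjusted p = 0.0951) and fibroblast markers (adjusted p = 0.832) no longer passed, and the median of profibrotic signalling was 0.03 although camera called it lower (adjusted p = 0.00711). All 10 LXR and cholesterol efflux genes were lower (median -0.21, adjusted p = 0.000223, and -0.13 without UW replicate 1), and so were 10 of 15 senescence genes (median -0.08, adjusted p = 0.0162). The remaining lower lists had adjusted p between 4.49e-05 and 0.0488. Of the 26 lists, 11 passed without any 1 of the 8 libraries, and the other 15 were each lost in 1 to 5 of these fits. Of the lists named in this paragraph, glucocorticoid response was lost without UW replicate 3, senescence and fibroblast markers without UW replicate 1 or mNIA replicate 4, and matrix turnover without UW replicate 1. In edgeR 0 genes passed (132 with an unadjusted p under 0.05, against 669 by chance), DESeq2 called 1 (Serpina3n) and limma-voom 1 (Ptx3). Without UW replicate 3 edgeR called 1 (Cyp1a1), and without the 4 libraries of low quality weight 0. The 4 memberships that passed when adjusted over the list alone were Mt2 in 2 lists, and Aldh1a2, a retinoic acid enzyme, and C3 among epicardial markers.

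**Figure D3:**
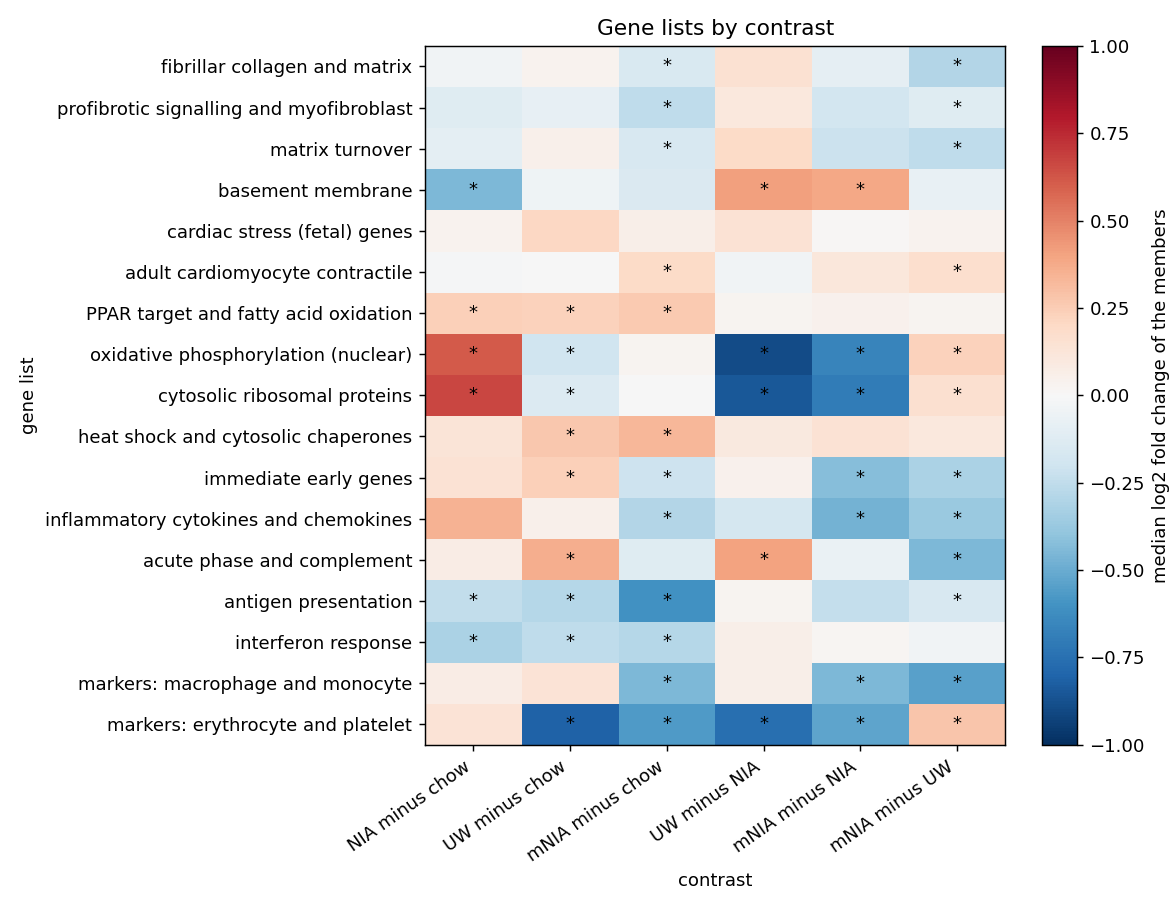
Median log2 fold change of the tested members of 17 gene lists (vertical axis) in the 6 pairs of diets (horizontal axis), coloured from blue (lower in the first diet) to red (higher); stars mark a camera adjusted p under 0.05 with the preset correlation, and 0 lists passed with an estimated correlation. The strongest colours are ribosomal protein and oxidative phosphorylation genes in UW minus NIA, with medians of -0.85 and -0.90.

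The effects of the diets relative to chow were compared across genes. The log2 fold changes of NIA and UW against chow correlated with r = 0.252 over 13381 genes, those of NIA and mNIA with 0.474 and those of UW and mNIA with 0.68. Sharing the chow libraries alone gave 0.471, 0.469 and 0.497 in simulated groups without any diet effect. Genes were drawn independently there, without the library structure of the real data. When the chow libraries were split 2 and 2 between the contrasts, the mean r over 6 splits was -0.05, 0.117 and 0.123, with ranges of -0.166 to 0.129, -0.029 to 0.317 and -0.059 to 0.262. Genes are not independent replicates, so no p-value is given.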

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

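The tests of A and T runs, of a shared diet effect, of depth in NIA replicate 4 alone, of NIA replicate 4 as sole source, of transcript length and of reads split between genes were chosen after the result was seen, and so was the removal of 4 libraries. The other splits of the libraries and the thinning of all libraries were chosen before.

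DESeq2 called 329 genes higher in NIA than in chow or UW. A diet effect shared by the NIA animals cannot be told apart: the median of these genes, picked for being high in NIA, lay above chow (log2) by 0.12 in NIA replicate 2, within the chow range of -0.17 to 0.25, but by 0.46, 0.67 and 2.05 in replicates 3, 1 and 4. With all libraries thinned to the shallowest the median stayed at 2.04 in replicate 4, which argues against a mere difference in depth from chow. Replicate 4 is itself the shallowest, so its own counts were unchanged, and the genes were picked from data that include its high values. Noise of low depth within that library therefore stays open. For replicate 1 the median was 0.65, and depth there cannot be told apart, because the bound set in advance was already missed before thinning. Counting of A- or T-rich reads to genes that hold a long run may account for part of the set: 30% of the called genes hold a run of at least 25 bases against 2.4% of the uncalled, a ratio of 12.46 (a minimum of 25 bases was chosen after values were seen; 20 gives 4.86 and 30 gives 36.7), while most called genes hold no such run. Without such genes DESeq2 called 15 genes in NIA minus chow and 245 in UW minus NIA.

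Ribosomal protein and oxidative phosphorylation genes were lower in UW than in NIA. Without NIA replicate 4 the difference of the mean list level (log2) was -0.34 ± 0.17 (SE), against -0.71 ± 0.40 with it, so a source in that library alone cannot be told apart from a wider difference at this spread. With each library's trend on transcript length removed it was -0.37 ± 0.22, which leaves the length trend open for the same reason, and with both it was -0.16 ± 0.09. In NIA replicates 1, 2, 3 and 4 the level was -0.19, 0.04, 0.32 and 1.56, against -0.45 to -0.07 in UW. A diet effect may remain and was not tested apart from NIA replicate 4 and the length trend. In chow the level was -0.19 to 0.03. With the length trend removed it was -0.14 to -0.03 in chow and -0.31 to -0.01 in UW, so the trend stays open for UW minus chow too. It was not weighed for these lists in the other comparisons, nor for any other list in any comparison.

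Phtf1os passed in mNIA minus chow. Reads split between it and the genes it overlaps, mostly Rsbn1, may account for part of its counts: with Rsbn1 and Phtf1 it summed to a whole number, within 0.01, in 15 of 16 libraries, while Phtf1os alone was whole in 3. Phtf1 took little part, with fractions only in chow replicate 4 and UW replicate 4 (73.98 and 74.94). Why such a split would give 2 counts in chow and 48 in mNIA was not tested. A diet effect on Phtf1os, or on the end of Rsbn1, stays open. The counts of Phtf1 were whole in all 4 mNIA libraries (52, 61, 59 and 63), so a share of its reads does not show there.

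In mNIA minus chow 1 of 35 splits, the real one, gave a gene (real 1, highest other 0). The smallest share these splits allow is 1 of 35, and 15 counts were compared. The 1 gene is also lost with DESeq2 and in most fits without 1 library, so chance is left open. For genes, a real count of 0 is reached by every split, so the comparison decides nothing there: 35 of 35 splits gave as many in NIA minus chow (highest other 1), UW minus chow (1), UW minus NIA (0), mNIA minus NIA (1918) and mNIA minus UW (0), and 100 of 100 drawn splits did in the mean of 3 diets minus chow (2680) and in any diet difference (519). For lists, 24 of 35 splits gave as many as the real 9 in NIA minus chow (highest other 24), 16 as many as 19 in UW minus chow (31), 11 as many as 18 in mNIA minus chow (25), 29 as many as 7 in UW minus NIA (29), 21 as many as 10 in mNIA minus NIA (27), 9 as many as 26 in mNIA minus UW (31), and 68 of 100 as many as 9 for the mean of 3 diets (30), so chance could not be excluded for any of them. The split with 1918 genes set NIA 1 with mNIA 1, 3 and 4 against the other 4 libraries, and the split with 2680 genes set chow 3, chow 4, NIA 3 and mNIA 2 against the rest. Splits with so many genes point to a structure of the libraries, which was not separated from diet. Levels of endothelial markers and citric acid cycle genes, picked after their values were seen, parted libraries within every diet. Chow replicate 3, NIA replicates 2 and 3, UW replicate 1 and mNIA replicate 2 had endothelial levels of 0.33 to 0.81. Their citric acid cycle levels were -1.21 to -0.38. In the other libraries these levels were -0.83 to 0.13 and 0.11 to 0.375.

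Among 372 groups of 4 libraries, 34 had 1 library far from the other 3 by Dixon's test for 4 values. Chance gives about 19 if values are independent and normal. Most measures were CPM of genes named in the text, some picked after their values were seen, and genes can move together. The excess over 19 is therefore no evidence by itself. Chow replicate 3 held 10 of them. It was high for Cdkn1a (23.4 CPM, others 11.7 to 12.8), Tagln (56.3, others 19.7 to 23.3), Cox7a1 (648, others 499 to 505), Zbp1 (5.89, others 2.03 to 2.34), Cxcl1 (4.71, others 1.61 to 1.95), Egr1 (184, others 24.8 to 51.2) and Fos (33.2, others 2.34 to 6.59). It was low for Acot2 (60.3 CPM, others 90.9 to 96.4) and Hspe1 (77.3, others 97.5 to 100). It was high for the share of counts on long-run genes (12.9%, others 6.61% to 7.23%). Chow replicate 4 held 0.338 CPM of Phtf1os, where the other chow libraries held 0.

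NIA replicate 4 was high for Rpl35 (1480 CPM, others 255 to 351), Rps24 (3370, others 670 to 802), Cox7a1 (3610, others 579 to 809) and Hspe1 (661, others 106 to 187), and low for Phtf1os (0.711, others 1.97 to 2.18). NIA replicate 1 was low for Fos (8.81 CPM, others 18.3 to 19.2), and NIA replicate 2 had 63 M counts (others 2.28 M to 5.74 M).

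UW replicate 1 was high for Col3a1 (457 CPM, others 202 to 245), Tgfb1 (48.5, others 32 to 34.5), Cyp26b1 (24.9, others 5.26 to 7.57) and Lox (10.3, others 5.91 to 6.23), and low for Myh6 (16700, others 28100 to 28700) and Gsta4 (47.4, others 73.4 to 77). UW replicate 3 was high for Acot1 (91.3, others 21 to 28.5) and Lmod1 (6.23, others 2.67 to 3.06), and UW replicate 2 for Fosb (11.2, others 1.04 to 2.53).

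In mNIA, replicate 2 was high for Nppa (207 CPM, others 112 to 119) and Tagln (40.7, others 16.6 to 20.3) and low for Acaca (14.1, others 20 to 20.6). Replicate 4 was high for Hspa1a (24.3 CPM, others 2.5 to 4.14) and low for Egr1 (14.2, others 28.6 to 31), replicate 1 was high for Fabp3 (4790, others 3940 to 4080) and replicate 3 low for Dbp (52.3, others 142 to 152).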

How the results depend on the processing

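The removal of 4 libraries of low quality weight, surrogate variables, the code block, thinning of NIA replicate 2 and removal of long-run genes were chosen after the result was seen; the rest was planned. Counts are of edgeR unless named, in the order NIA, UW and mNIA minus chow, UW minus NIA, mNIA minus NIA, mNIA minus UW, mean of 3 diets minus chow, any diet difference. The counts as reported were 0, 0, 1, 0, 0, 0, 0 and 0, and RLE size factors, no filter, over 1 CPM in 4 libraries, removal of the 10 top genes and removal of long-run genes gave the same counts. The 1 call of mNIA minus chow became 0 with upper-quartile scaling, the replicate block, the code block, thinning of NIA replicate 2 and 2 groups only. DESeq2 gave 127, 1, 0, 375, 3, 1, 0 and 174, and limma-voom with quality weights 28, 1, 1, 916, 1979, 1, 4 and 1980. DESeq2 without long-run genes gave 15, 1, 0, 245, 3, 1, 0 and 69, the fall after removal of 409 tested genes. With 3 surrogate variables the fit gave 1, 10, 1, 0, 0, 8, 2 and 5, the 5 being 2210407C18Rik, Abca1, Gfpt2, Phtf1os and Trpc2. Removal of the 4 libraries, which narrows the spread within diets by construction, gave 224, 1, 0, 1627, 3184, 0, 0 and 1374. Leaving out 1 library gave 0 to 116 (116 without NIA replicate 2), 0 to 0, 0 to 1, 0 to 217 (217 without NIA replicate 2), 0 to 0, 0 to 1 (Cyp1a1, 1 call without UW replicate 3, also in UW minus NIA and any diet difference), 0 to 0 and 0 to 110 (110 without NIA replicate 2). The 1 of mNIA minus chow was kept without chow replicate 4 or mNIA replicate 3.

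For lists, camera called 9, 19, 18, 7, 10, 26 and 9 in the first 7 comparisons; with an estimated correlation and with fry each was 0. Removal of the 4 libraries gave 19, 11, 19, 18, 28, 33 and 9, surrogate variables gave 4 in mNIA minus chow, and no filter gave 14 for the mean of 3 diets. Leaving out 1 library gave 5 (without NIA replicate 1) to 10, 11 (without UW replicate 2) to 23, 7 (without mNIA replicate 4) to 23, 6 to 9, 6 (without NIA replicate 2) to 14, 20 to 30, and 8 to 16 (without chow replicate 1). With chow libraries split 2 and 2 the correlations of 0.252, 0.474 and 0.68 became -0.05, 0.117 and 0.123, where no chow library was shared and each contrast kept 2 of them, and the 2 changes were not separated. Of the log2 fold changes of named genes, refitted in all settings but upper quartile, limma-voom, over 1 CPM, removal of the 10 top genes and 2 groups only, 13356 kept their side of the threshold and, if uncalled, moved by under 1 SE, 570 uncalled ones moved by more, 160 came past the threshold, 12 (all of Phtf1os in mNIA minus chow) no longer passed it, and 0 that were called in either fit changed sign. Except where stated, the cause was not tested. In simulated data, with genes drawn independently, 27% to 45% of 2-fold and 84% to 94% of 4-fold changes were recovered.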

Other observations

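The comparison without 4 libraries, the check of the library code numbers and the lengths of the called genes were chosen after the result was seen; the pairing of replicate numbers was planned.

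Lymphatic and metal-handling genes were not described above for mNIA and UW. The lymphatic endothelial list was lower on mNIA than on UW (6 of 8 members, median log2 fold change -0.34, camera adjusted p = 0.000143, adjusted p = 0.0953 with an estimated correlation), with Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, at -0.65 ± 0.21. Metal handling genes were lower as well (13 of 16, median -0.20, adjusted p = 0.000223, adjusted p = 0.0953 with an estimated correlation), with the copper carrier gene Cp at -0.54 ± 0.25. Slc2a1, the basal glucose transporter in the hypoxia list, was at -0.58 ± 0.20; that list had 10 of 18 members lower (median -0.09, adjusted p = 0.0169, adjusted p = 0.183 with an estimated correlation), and its call was kept in 3 of 8 fits without 1 library, against 8 of 8 for the lymphatic and metal lists (lymphatic median -0.17 at the weakest, without mNIA replicate 3).

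Without chow replicate 3, NIA replicates 1 and 4 and mNIA replicate 2, edgeR called 1627 genes in UW minus NIA and 3184 in mNIA minus NIA, with 2 NIA animals left. These libraries were removed for a low weight, that is for lying far from their diet mean, so the spread was narrowed by construction. The 1139 genes higher in UW had a median transcript length of 5048 bases and the 488 lower ones 2283, against 3424 over all tested genes. The 1928 genes higher in mNIA had a median of 4607 bases and the 1256 lower ones 2578. Across genes the Spearman rho of the log2 fold change with length was 0.37 and 0.3. It was not confined to the comparisons with many calls, since it was 0.32 in UW minus chow (1 gene called), 0.28 in mNIA minus chow (0 called), -0.21 in NIA minus chow (224 called), 0.02 in mNIA minus UW and 0.13 in the mean of 3 diets minus chow (0 called in each).

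Replicate numbers did not pair the libraries of different diets: of 24 pairs with the same number, 9 had a correlation above 0.1 after diet means were removed, and the values ran from -0.579 to 0.607. Chow replicate 3, NIA replicate 3 and mNIA replicate 2, whose library codes all end in 3, correlated with one another at 0.524 to 0.712, while UW replicate 3 correlated with them at -0.116 to -0.029. No 2 libraries of a diet were copies of each other (chi-square per degree of freedom at least 4.55).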
